A study of Mus musculus with 16 samples.

How the data were processed

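RNA from mouse liver was profiled on 16 Illumina arrays, 4 per group. Per the labels, total RNA was converted to biotinylated cRNA and the arrays were read with GenomeStudio 2009.1. The deposited signal table holds, per probe and sample, an intensity that was background-subtracted but not normalized between arrays, with values under 0. Beside each intensity the deposited table holds a detection p-value. The authors also deposited a table of intensity values on the linear scale that were quantile-normalized between arrays, used here, on the log2 scale, only as an alternative. No paper was used, and the labels do not say that the 16 samples are separate animals, so p-values measure the spread between samples.

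Signals were processed in R 4.3.3 with limma 3.58.1. Background was modelled by normexp from the detection p-values with an offset of 16, followed by quantile normalization and log2. Probes detected (detection p under 0.05) on at least 4 arrays were kept: 12248 of 25697 probes, for 9265 of 18138 symbols. The brightest kept probe stood for each gene. Of the symbols, 17213 were found in the RefSeq gene table and 925 were not. 9145 probes were never detected. Probes of the same gene need not behave alike: of the genes called between the diets that had several kept probes, 153 of 528 in WT and 198 of 538 in KO had probes with opposite signs, some of them with changes near 0. Nr0b2, Cd36, Tnf and Ccl2 were detected on 0 arrays, so these were not tested. Some genes of the fixed set are not reported here.

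A linear model with a mean per group and a shared variance per gene was fitted with lmFit and eBayes. The 5 comparisons were KO minus WT on each diet, high cholesterol minus chow in each genotype, and the interaction. Tests were the two-sided moderated test of limma with Benjamini-Hochberg adjustment over all genes of a comparison, at 0.05. Where no array of a group detected any probe of a gene, its fold is given as a lower bound, with each array of that group raised to at least the lowest signal detected on that array.

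Gene sets were 24 pathway and 12 cell type lists, holding 393 measured genes, 5 of them in more than 1 list. They were tested with limma camera at its preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were the alternatives. The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text could name Met, the 8 largest changes in each direction past the threshold, up to 4 members per list with the smallest p, and a fixed set of genes of bile acid, cholesterol and stress biology. Genes named outside it are marked as chosen after their values were seen.

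The alternatives were no background correction, cyclic loess or median scaling, the authors' normalized values, no detection filter or a stricter one (detection p under 0.01 on all 4 arrays of at least 1 group), the mean of probes, probes tested singly, the replicate number as a block, only the groups compared, a variance trend with robust estimation, array weights, a log2 change of at least 1, and each array left out in turn. Leaving out 3 arrays together was chosen after seeing the data. A block on the slide was not run, because the files give no slide.

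The procedure was tested on simulated data with the gene means and spreads of these arrays and 200 changed genes among 9265. It recovered 18 of 67 genes changed by a log2 of 0.5, 56 of 67 changed by 1 and all 66 changed by 2, with 8 false calls. The simulated noise was independent between genes and arrays, so these false calls do not cover variation that genes or samples share. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.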

Results

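Liver RNA from 16 mouse samples was measured on Illumina bead arrays, 1 array per sample. The samples formed 4 groups of 4: wild type (WT) and conditional c-Met knockout (KO) mice, each fed regular chow or a high cholesterol diet for 30 days. The high cholesterol diet held 2% cholesterol and 0.5% sodium cholate, a bile acid salt. c-Met is the receptor for hepatocyte growth factor. Between 10028 and 11952 of the 25697 probes were detected per array, and the 75th percentile of the signal ranged from 61.4 to 113 intensity units. The number of arrays per group limits the precision of every comparison. Values below are log2 fold changes with their standard error from limma (n = 4 arrays per group), and folds are on the linear scale.

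Met, the gene targeted in the knockout, was near background in all groups. Its probe was detected on 7 of 16 arrays: 2 of 4 chow WT, 3 of 4 chow KO, and 1 of 4 in each high cholesterol group. The KO minus WT difference was 0.38 ± 0.19 on chow (adjusted p = 0.329) and -0.05 ± 0.19 on the high cholesterol diet (adjusted p = 0.969). Where the probe lies relative to the deleted part of the gene is not given in the sources used here. The Met signal therefore could not check the genotype labels.

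The comparison of the diets in WT mice asked which liver transcripts differ after 30 days of cholesterol and cholate. Cyp8b1, the sterol 12alpha-hydroxylase of bile acid synthesis, fell by 7.97 ± 0.14; it was detected on 1 of 4 high cholesterol arrays, so the size depends on the background level. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 5.22 ± 0.61, also detected on 1 of 4 (WT replicate 1); without that array it was at least 43.4-fold lower. Fdps, the farnesyl diphosphate synthase of cholesterol synthesis, fell by 3.16 ± 0.33 (8.93-fold). The glutathione transferase Gsta1 rose by 6.03 ± 0.56 (65.3-fold). Gpnmb, a glycoprotein of lipid-laden macrophages, was detected on 0 of 4 chow and 4 of 4 high cholesterol arrays, at least 13-fold higher.

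Of 21 measured genes of cholesterol synthesis and uptake, 17 fell and 0 rose in WT, with the same counts adjusted over the list alone (camera adjusted p = 1.82e-12; adjusted p = 0.141 with an estimated correlation). Cyp51, lanosterol demethylase, fell by 2.34 ± 0.28. Sqle, squalene epoxidase, fell by 2.68 ± 0.39 and was detected on 2 of 4 high cholesterol arrays. Of 12 bile acid synthesis genes, 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.141 with an estimated correlation). Cyp7b1, the oxysterol hydroxylase, fell by 2.05 ± 0.30.

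Among 13 genes of bile acid and sterol transport in WT, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.151 with an estimated correlation). The sterol exporters Abcg5 and Abcg8 rose 2.82-fold and 2.91-fold, with standard errors of 0.18 and 0.24 on the log2 scale. Abcb11, the bile salt export pump, rose 1.99-fold, with a standard error of 0.21 on the log2 scale and arrays of the groups overlapping. Ostb, a bile acid exporter of the sinusoidal membrane detected on 3 of 4 chow arrays, rose by 2.29 ± 0.28. Of 10 targets of the sterol sensor LXR, which include Abcg5 and Abcg8, 6 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.216 with an estimated correlation). Lpl, lipoprotein lipase, rose by 2.11 ± 0.38. Srebf1 was at -0.44 ± 0.39 and did not pass (adjusted p = 0.425).

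Of 20 targets of the oxidative stress regulator NRF2, 15 rose and 0 fell in WT, with the same counts adjusted over the list alone (camera adjusted p = 1.83e-08; adjusted p = 0.141 with an estimated correlation). Gstm1 rose by 1.81 ± 0.12, and Gstm3, detected on 0 of 4 chow arrays, was at least 5.91-fold higher. These transferases have close paralogs, to which their probes might bind in part. Heme oxygenase Hmox1 rose by 0.71 ± 0.19, while the quinone reductase Nqo1 was at 0.01 ± 0.22 (adjusted p = 0.978). Of 12 measured cytokine, chemokine and adhesion genes 5 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0492; adjusted p = 0.522 with an estimated correlation). This call was lost without any 1 of 8 arrays, with camera adjusted p up to 0.149 (without high cholesterol WT replicate 4). The leukocyte adhesion molecules Vcam1 and Icam1 rose by 1.36 ± 0.18 and 1.44 ± 0.20.

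Of 9 recruited macrophage markers, which hold lysozyme and Clec7a under several symbols, 8 rose in WT and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.59e-07; adjusted p = 0.141 with an estimated correlation). Of 17 matrix and fibrosis genes 10 rose and 0 fell, again also when adjusted over the list alone (camera adjusted p = 3.18e-05; adjusted p = 0.141 with an estimated correlation). The collagen genes Col1a1 and Col4a1 rose by 1.30 ± 0.21 and 0.82 ± 0.14, with Col1a1 detected on 1 of 4 chow arrays, and the macrophage elastase Mmp12 was at least 2.72-fold higher. Of 18 cell cycle genes 9 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 2.07e-05; adjusted p = 0.366 with an estimated correlation). Cyclin D1 gene Ccnd1 rose by 3.02 ± 0.26, and Mcm6, of the replicative helicase and detected on 3 of 4 chow arrays, by 2.23 ± 0.34. Of 9 genes known to be higher in male liver, 4 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00233; adjusted p = 0.285 with an estimated correlation), among them Susd4 by 3.57 ± 0.23.

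In total 2354 of 9265 genes passed an adjusted p of 0.05 between the diets in WT, 1265 higher and 1089 lower on the high cholesterol diet. The balance turned with median scaling (1099 higher, 1315 lower) and with a stricter detection filter (905 and 992). Over all genes the arrays of the groups did not overlap for 2350, 25.4%, against 2.86% by chance. Among the genes that passed it was 1893, 80.4%; this held for 23 of the 24 genes named as passing, Abcb11 excepted. The background of the arrays differed with the diet: its SD over never detected probes was 4.47 to 5.51 on chow arrays and 6.54 to 8.08 on high cholesterol arrays. No array date or slide is given.

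**Figure D1:**
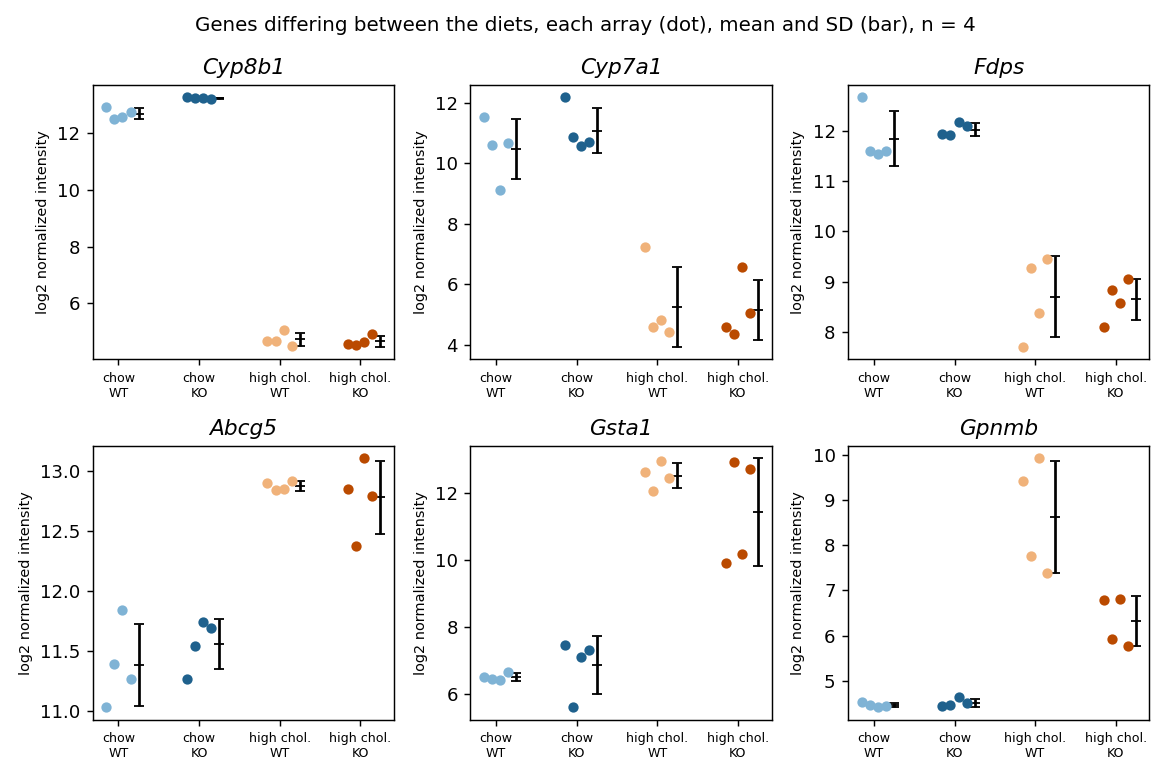
Log2 normalized intensity of 6 genes on each array (dots), with mean and SD (bars), n = 4 per group. Cyp8b1, Cyp7a1 and Fdps lie lower, and Abcg5, Gsta1 and Gpnmb higher, on the high cholesterol diet in both genotypes.

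The same diet comparison in c-Met KO mice showed Cyp8b1 detected on 0 of 4 high cholesterol arrays, at least 278-fold lower than on chow. Cyp7a1, detected on 1 of 4 high cholesterol arrays, fell by 5.93 ± 0.61, and Fdps fell by 3.39 ± 0.33. Sqle was at least 10.7-fold lower. Gsta1 rose by 4.57 ± 0.56 (23.8-fold), Abcg5 by 1.22 ± 0.18, and S100a8, a calcium-binding protein of neutrophils detected on 3 of 4 chow arrays, by 3.48 ± 0.41 (11.2-fold).

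In KO, 17 of 21 cholesterol synthesis and uptake genes fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.05e-10; adjusted p = 0.296 with an estimated correlation). Of 12 bile acid synthesis genes 6 fell and 1 rose, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.296 with an estimated correlation). Of 13 bile acid and sterol transport genes 4 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.176). Of 10 LXR targets 6 rose and 0 fell, or 7 and 1 adjusted over the list alone, and of 20 NRF2 targets 12 rose and 0 fell, also when adjusted over the list alone. Their camera adjusted p were 0.0106 and 1.23e-05; each had adjusted p = 0.296 with an estimated correlation. Of 15 acute phase genes, which encode plasma proteins of inflammation, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00581; adjusted p = 0.471 with an estimated correlation). Ceruloplasmin gene Cp rose by 1.10 ± 0.18 and the serum amyloid gene Saa3 by 2.18 ± 0.46.

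Of 9 male-high genes 5 fell in KO and 0 rose, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000163; adjusted p = 0.296 with an estimated correlation). Of 6 measured female-high genes 4 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.401 with an estimated correlation). The cytochrome P450 gene Cyp2b9, detected on 1 of 4 chow arrays, rose by 3.57 ± 0.57, and Cyp2b13, detected on 0 of 4 chow arrays, was at least 3.33-fold higher. Of 9 recruited macrophage markers 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00197; adjusted p = 0.359 with an estimated correlation), with Gpnmb at least 2.6-fold higher. Of 10 Kupffer cell markers, of the resident liver macrophages, 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.658 with an estimated correlation), and Emr1 rose by 1.20 ± 0.31. Of 12 cytokine and adhesion genes 5 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0374; adjusted p = 0.471 with an estimated correlation). Leaving out 1 array ended the calls of the Kupffer list for 2 arrays and the cytokine list for 3, with camera adjusted p up to 0.271 and 0.23 without high cholesterol KO replicate 3. The female-high call ended for 5 arrays, with camera adjusted p up to 0.158 without high cholesterol KO replicate 2.

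In KO 2 of 17 matrix genes rose and 0 fell, and 2 of 18 cell cycle genes rose and 0 fell, with the same counts adjusted over each list alone. Neither list passed (camera adjusted p = 0.531 and 0.351), and the matrix list had a median of -0.03 with an upward camera direction. Col1a1 was at 0.27 ± 0.21 (adjusted p = 0.341). In total 2559 genes passed, 1411 higher and 1148 lower, but 1016 higher and 1347 lower with median scaling, and 949 and 951 with a stricter detection filter. Over all genes 2805, 30.3%, had no overlap between the arrays of the groups, against 2.86% by chance. Among the genes that passed it was 2121, 82.9%, with all 15 named as passing.

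**Figure D2:**
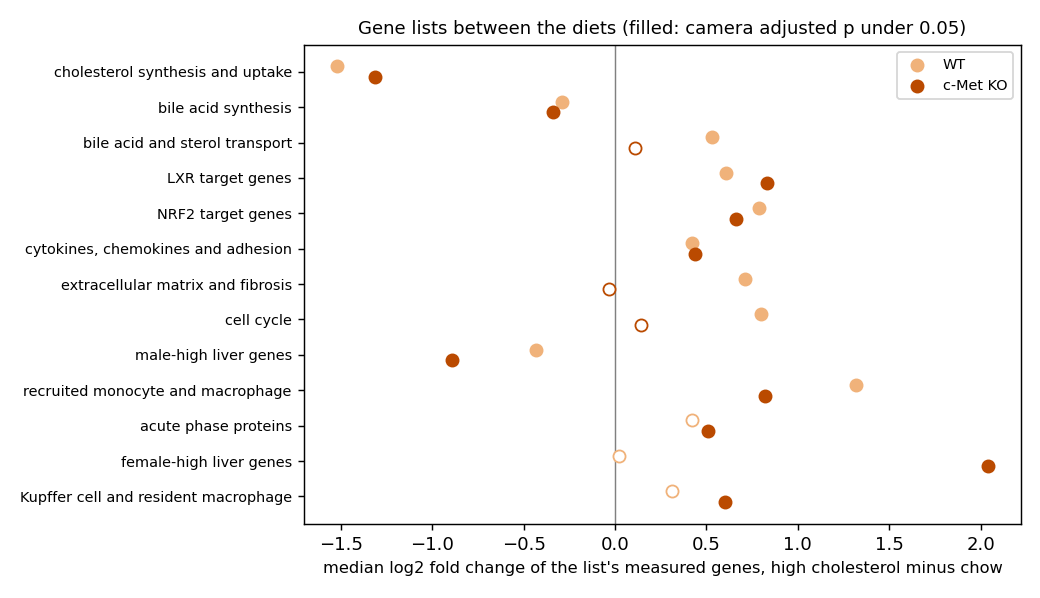
Median log2 fold change, high cholesterol diet minus chow, of each gene list that passed camera (preset correlation) in either genotype; filled points passed. Of the 36 lists 10 passed in each genotype, and 0 with an estimated correlation.

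Between the genotypes the diet responses shared 844 higher and 532 lower genes, where independent lists would share 193 and 135. Abcg5, Gsta1, Gpnmb and Ccnd1 passed as higher in both, and Cyp8b1, Cyp7a1, Fdps and Cyp51 as lower in both. 1 gene passed in opposite directions. Of the genes called in WT, 94.5% had the same sign in KO.

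**Figure D3:**
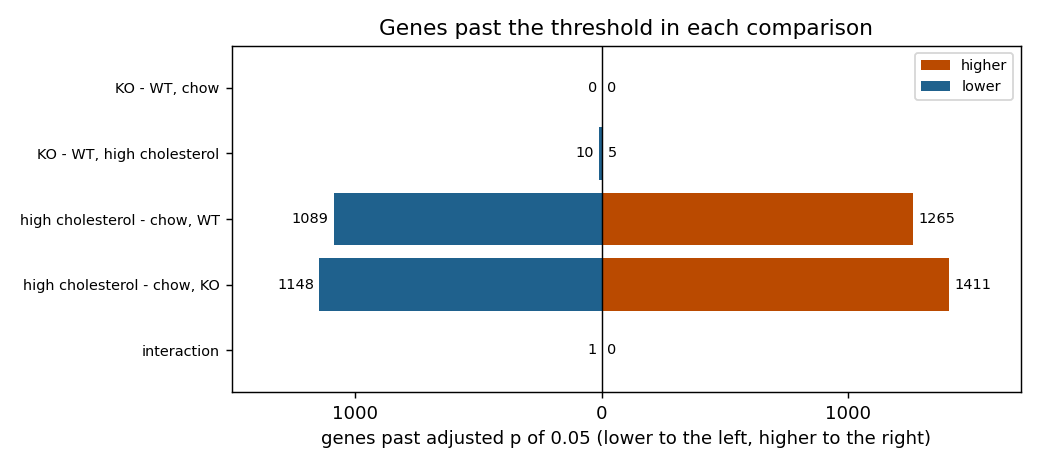
Number of genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left of 0. The diet comparisons held 2354 and 2559 genes, the genotype comparisons 0 (chow) and 15 (high cholesterol), and the interaction 1. The order of the genotype counts depended on the fit and the threshold. In limma fits on the arrays of each diet alone, 74 genes passed on chow and 0 on the high cholesterol diet. At an unadjusted p under 0.05 in the main limma fit the counts were 1470 and 905.

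The comparison of KO with WT on the high cholesterol diet asked what the loss of c-Met changes under that diet. Smpdl3b, a lipid-modifying phosphodiesterase of the cell surface, fell by 2.38 ± 0.25 (5.21-fold). Gpnmb fell by 2.30 ± 0.41 (4.92-fold), Mcm6, detected on 2 of 4 KO arrays, by 2.04 ± 0.34, Cd63, a tetraspanin of lysosomes, by 1.48 ± 0.25, and Col4a1 by 0.86 ± 0.14. Higher in KO were Cyp2b13, by 1.73 ± 0.29 and detected on 2 of 4 WT and 4 of 4 KO arrays, and Cyp2c50, a drug-metabolising enzyme, by 0.94 ± 0.14. In KO against WT, 15 genes passed, 5 higher and 10 lower, and all 15 had no overlap between the groups, as had 363 of all genes (3.92%, against 2.86% by chance). Smpdl3b and Cyp2c50 passed without any 1 array, while Col4a1 did not pass without WT replicate 3 (adjusted p = 0.0728), Mcm6 without KO replicate 2 (0.062), Cd63 and Cyp2b13 without either of these arrays (0.0539 to 0.0728), and Gpnmb without WT replicate 1 or 3 or KO replicate 2 or 4 (0.0673 to 0.117).

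Of 17 matrix and fibrosis genes 1 fell and 0 rose on this diet, or 8 and 0 adjusted over the list alone (camera adjusted p = 6.46e-08; adjusted p = 0.0977 with an estimated correlation; fry adjusted p = 0.025). Lum, a matrix proteoglycan, was at -0.92 ± 0.22 (adjusted p = 0.116) and Col1a1 at -0.85 ± 0.21 (adjusted p = 0.136). Of 18 cell cycle genes 1 fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 8.29e-06; adjusted p = 0.478 with an estimated correlation). Their mean difference went from -0.51 to -0.2 without WT replicate 3 (camera adjusted p = 0.0327). Of 9 recruited macrophage markers 1 fell and 0 rose, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.000654; adjusted p = 0.478 with an estimated correlation). Of 6 female-high genes 1 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.000178; adjusted p = 0.336 with an estimated correlation). Cyp2b9 was at 2.82 ± 0.57 and was detected on 2 of 4 WT arrays (adjusted p = 0.067). As a mean log2 deviation from all arrays, the female-high list overlapped between the genotypes. It was 0.03 in KO replicate 4, below WT replicates 1 (0.14) and 2 (0.38). In both genotypes replicates 1 and 2 lay above replicates 3 and 4.

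Of 17 drug-metabolising cytochrome P450 genes 2 rose in KO and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0159; adjusted p = 0.478 with an estimated correlation). Of 11 endothelial markers 0 passed, or 1 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.0263; adjusted p = 0.478 with an estimated correlation). Lyve1, an endothelial hyaluronan receptor detected on 3 of 4 KO arrays, was at -1.11 ± 0.25 (adjusted p = 0.112). Leaving out 1 array ended the P450 and the endothelial call for 2 arrays each, with camera adjusted p up to 0.191 (without KO replicate 2) and 0.209 (without KO replicate 4). The count of 15 genes, from the fit on all 16 arrays, became 5 without WT replicate 3, 7 without KO replicate 2, 24 without KO replicate 3 and 25 without WT replicate 4. In a separate limma fit on the 8 high cholesterol arrays alone 0 genes passed.

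**Figure D4:**
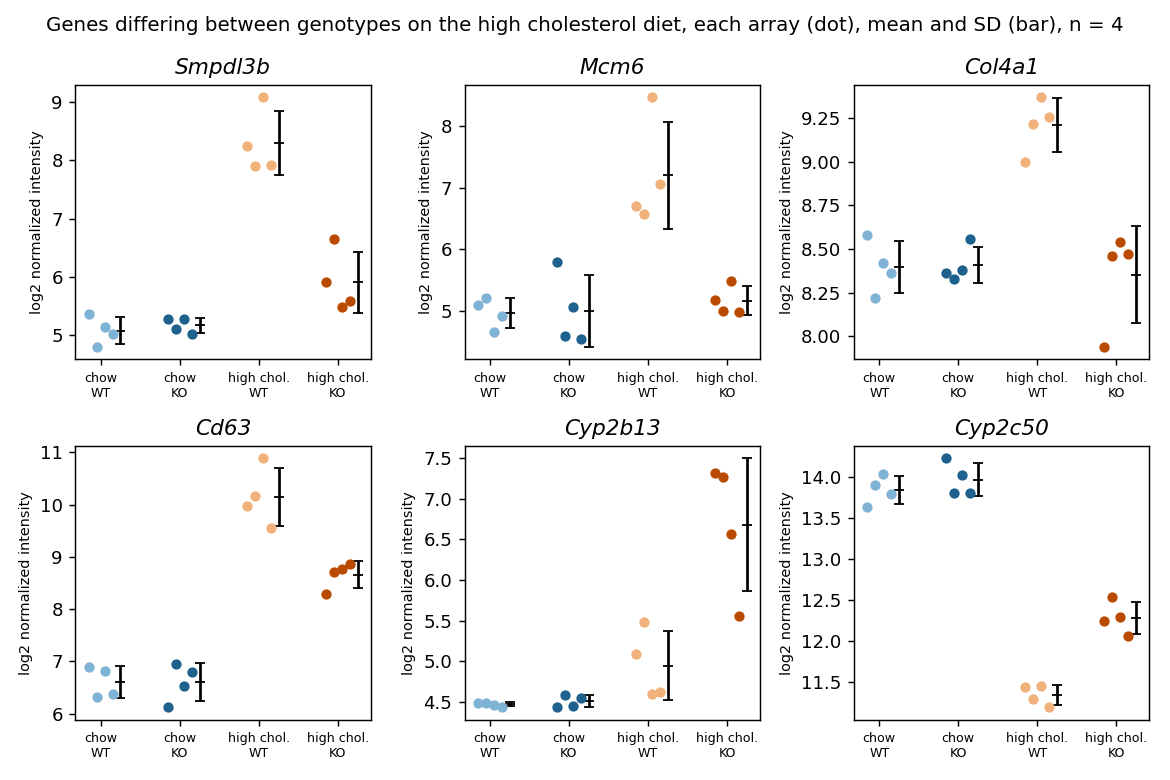
Log2 normalized intensity on each array (dots), with mean and SD (bars), n = 4 per group, of 6 genes that passed between KO and WT on the high cholesterol diet. Smpdl3b, Mcm6, Col4a1 and Cd63 lie lower and Cyp2b13 and Cyp2c50 higher in KO on that diet.

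The interaction asked whether the genotype difference depends on the diet, which also tests whether the matrix and cell cycle responses differ between the genotypes. Smpdl3b alone passed among 9265 genes, with an interaction of -2.47 ± 0.36 (adjusted p = 0.0222), and was detected on 3 of 4 chow WT arrays and all others. Of the lists, the matrix genes had a median interaction of -0.73, the cell cycle genes -0.55, the recruited macrophage markers -0.33 and the female-high genes 1.43. The cell cycle median was -0.21 without high cholesterol WT replicate 3, and the macrophage median -0.5 without high cholesterol KO replicate 3. Over all genes 0 members of each passed. Adjusted over the list alone, 6 of 17 matrix, 3 of 18 cell cycle and 1 of 9 macrophage genes were lower and 3 of 6 female-high genes higher. Camera adjusted p were 1.98e-06, 2.06e-05, 0.00571 and 0.000631. With an estimated correlation none passed: the matrix list had adjusted p = 0.191 with an estimated correlation, the female-high list adjusted p = 0.469 with an estimated correlation, and the cell cycle and macrophage lists adjusted p = 0.751 with an estimated correlation. The Smpdl3b call ended without chow WT replicate 2, 3 or 4, without any 1 chow KO array, or without high cholesterol KO replicate 1, with adjusted p up to 0.0951 (without chow WT replicate 2). Over 28 settings in all its adjusted p ran from 0.000923 to 0.121, and 12 ended the call, among them the replicate number as a block.

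The comparison of KO with WT on chow asked what c-Met loss changes without the diet. No named gene passed with limma over 9265 genes: 0 genes had an adjusted p under 0.05, 1470 had an unadjusted p under 0.05 where 463 would by chance, and the lowest adjusted p was 0.0646. Selenbp2, a selenium-binding protein, was at -1.69 ± 0.41 and Irs2, an adaptor of insulin signalling, at 1.31 ± 0.32 (adjusted p = 0.145 for both). The clock genes Per1 and Cry2 were at -1.02 ± 0.30 and -0.73 ± 0.22 (adjusted p = 0.172 for both). Ccl9, a chemokine gene chosen after its values were seen, was at -1.25 ± 0.20 (adjusted p = 0.0646).

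Of the 36 lists 0 passed on chow with camera, with an estimated correlation or with fry. Adjusted over the list alone, the 12 clock genes held 1 higher and 2 lower, and over all genes 0; 30 of the 36 lists had equal counts either way. In a fit on the 8 chow arrays alone 74 genes passed, 47 higher and 27 lower in KO. With array weights in the fit on all 16 arrays 351 passed. 1272 genes, 13.7%, had no overlap between the chow genotypes, where chance gives 2.86%.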

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

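The tests of array background, array batch and gene lists, the share of hepatocyte RNA, 1 array behind the cell cycle and macrophage scores, strain variants and the genotype acting on Tpmt were chosen only after the result was seen. A sample stood apart from the other 3 of its group, by its gap to the nearest relative to the range of the group, in 17 of the 148 groups tested over named genes and measures of the arrays, where chance gives about 7 (5%). Since 6 genes were chosen after their values were seen, part of this excess is built in: without them it was 10 of 130, where chance gives 6.5. Chow WT replicate 1 held 6 of the 17. On it the pancreatic enzyme genes Ela2a and Ctrl stood at a log2 intensity of 12.36 and 10.25, against at most 5.42 and 5.17 on the others (gap over range 0.939 and 0.87). Irs2 was low there (0.868), and Col1a1 (0.959), Fdps (0.937) and Gstm1 (0.867) were high. On chow KO replicate 4 the fat cell gene Cfd stood at 11.15 against at most 5.42 (0.874), and on chow KO replicate 2 Ctrl at 5.31 against at most 4.84 (0.929). The 6 genes chosen late are Ela2a, Ctrl and Ccl9, and Hamp2, Corin and H2-Bl below.

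Of the high cholesterol arrays, KO replicate 1 was low for Col4a1 (gap over range 0.873) and S100a8 (0.937), and KO replicate 3 was high for Saa3 (0.846) and low for Tpmt (0.868). WT replicate 1 was high for Cyp7a1 at 7.22 against at most 4.81 (0.858), which makes it the array of that group that detected the gene. The on or off genes named below stood apart as well: Hamp2 was low on chow WT replicate 3 (0.96), and H2-Bl was high on chow KO replicate 2 (0.979) and high cholesterol WT replicate 1 (0.913) and low on high cholesterol KO replicate 4 (0.885).

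The interaction test passed for Smpdl3b (-2.47, adjusted p = 0.0222), but 12 of 28 settings ended this call and chance cannot be excluded for it (13 of 100 splits gave at least 1 gene). With camera it passed for the matrix (1.98e-06), cell cycle (2.06e-05), female-high (0.000631) and recruited macrophage lists (0.00571). None of these lists passed with an estimated correlation.

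The genes called between the diets, 2354 in WT and 2559 in KO, came from groups whose arrays also differed in background. Against background alone as the cause, 24.1% in WT and 22.3% in KO of the 3120 genes with a signal over 20 times the highest background SD on every array were called, against 25.4% and 27.6% of all genes. An array batch blind to function was weighed by 72 tests (36 lists, each direction). They set the genes called alike in both genotypes against the number that genes of like brightness give. In 6 tests there were more (each exact p under 0.001, chance 0.072), which argued against such a batch for these lists. They were cholesterol synthesis and uptake (16 of 21 lower, 1.35 from like brightness, exact p = 6.76e-16), bile acid synthesis, NRF2 and LXR targets, recruited macrophages and P450. The exact p treats the genes of a list as independent, but they can move together (estimated correlation 0.338 in the cholesterol list). The macrophage list also holds lysozyme and Clec7a under several symbols. These p-values may therefore be too small. For genes outside these lists a share of an array batch cannot be told apart from the diet. The labels name no batch, but the lowest background SD on a high cholesterol array (6.54) lay above the highest on chow (5.51). Signals of never detected probes correlated by 0.39 to 0.43 (Spearman) between high cholesterol arrays. Between chow arrays it was 0.1 to 0.16, and across the diets 0.09 to 0.16. In a limma fit over all probes 125 of 9145 never detected probes were called between the diets in WT and 239 in KO. Between the genotypes 0 were called on either diet. Of the 12248 kept probes only 4 on chow and 7 on the high cholesterol diet were called between the genotypes, so this 0 says little. The diet stays open as the biological explanation, as a hypothesis.

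The matrix, cell cycle and recruited macrophage lists were lower in KO than in WT on the high cholesterol diet with camera, but not with an estimated correlation (adjusted p = 0.0977, 0.478 and 0.478), and over all genes 1 member of each passed. No single array carried the matrix difference (without any 1 array camera adjusted p at most 1.38e-05, median -0.5 or lower without any 1 of the 8 high cholesterol arrays) or that of the macrophage score (-0.6, and -0.39 without WT replicate 3), but without WT replicate 3 the cell cycle difference went from -0.51 to -0.2, so 1 array might carry much of it. A larger share of hepatocyte RNA in KO would by itself lower the markers of resident and recruited macrophages alike. The Kupffer minus recruited score was 0.87 higher in KO (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). The permutation ignored replicate numbers. The recruited list was taken up because it fell in these arrays, which builds in part of this difference. The Kupffer score alone was 0.27 higher in KO, with KO replicate 3 at 1.41. The test therefore cannot exclude a larger hepatocyte share beside fewer recruited macrophages. Whether fewer recruited macrophages explain the matrix score cannot be told apart: with their score as a covariate the difference went from -0.45 to -0.39 (95% interval -0.82 to 0.03), and that of the cell cycle score to -0.05 (-0.78 to 0.67). An effect of the genotype stays open as a hypothesis.

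Within a diet 10 genes, among them Tpmt, Hamp2, Corin and H2-Bl, were on or off by array, which strain variants segregating in the mixed background might cause. In 3 of the 10 a chromosomal neighbour correlated with the gene over the arrays, in either direction, beyond chance. They were Hamp2 (r = -0.79), Corin (0.83) and Tpmt (0.76), where chance gives 0.5 genes (exact binomial p = 0.0115). Whether these neighbours were themselves on or off was not tested. Corin and Tpmt lay just under the limit (exact p = 0.0465 and 0.0485). The exact calculation replaced random draws, which gave 3 genes for only 8 of 20 seeds and 1 or 2 for the others (binomial p for 2 genes 0.0861), so the excess is uncertain, and leaving out neighbours whose names share 3 letters was also chosen late: with 4 letters H2-Bl joined, through a gene of its own family, for 4 of 10 (exact binomial p = 0.00103). A variant within a gene needs no such neighbour. Whether the genotype acts on Tpmt alike in both diets cannot be told apart: its interaction of -4.41 ± 0.84 did not pass over all genes (adjusted p = 0.148).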

How the results depend on the processing

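Leaving out 3 arrays together (chow WT replicate 1, chow KO replicate 4 and high cholesterol KO replicate 3) was chosen only after the data were seen. Under the settings tried, 1323 of 1359 values of called named genes kept their direction and their side of the threshold, 36 no longer passed and 0 reversed. All 36 fell on the genotype comparison on the high cholesterol diet or on the interaction, and 0 on the diet comparisons. The Smpdl3b interaction lost its call in 12 settings, Gpnmb in 8 and Cyp2b13 in 5. Every named genotype call was lost in some setting. Of the values of called lists, 592 of 660 kept both, 68 no longer passed and 0 reversed. Unless a cause is named, the cause was not tested.

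On chow, the count of genes between KO and WT was 0 and became 7 without background correction, 3 with cyclic loess, 2 with median scaling, 5 with the authors' values, 3 without a detection filter, 3 with the mean of probes, 2 with probes tested singly, 2 with the replicate block, 74 with only the groups compared, 1 with a trend and robust variance, 351 with array weights (173 higher, 178 lower) and 1 without the 3 arrays. Leaving out 1 array gave 0 to 8, the highest without high cholesterol WT replicate 3. On the high cholesterol diet the count of 15 became 26 with median scaling, 0 with only the groups compared and 6 without the 3 arrays, and 5 to 25 without 1 array. The median SD within a group was 0.22 in WT and 0.181 in KO on chow, and 0.255 and 0.246 on the high cholesterol diet.

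The interaction count of 1 became 0 without background correction, without a detection filter and with the replicate block, 3 with median scaling and with array weights, and 4 with the authors' values. Leaving out 1 array gave 0 to 9, the highest without high cholesterol WT replicate 4. A log2 change of at least 1, which by construction keeps fewer genes, left 503 genes between the diets in WT, 506 in KO and 253 in both. Leaving out 1 array gave 1931 to 2457 in WT, 1956 to 2701 in KO and 1141 to 1325 in both. The Met difference was 0.27 to 0.54 on chow and -0.14 to 0.05 on the high cholesterol diet without 1 array.

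The lists past the threshold numbered 0 with an estimated correlation in each comparison. With fry they numbered 16 between the diets in WT, 18 in KO, 1 between the genotypes on the high cholesterol diet and 0 in the interaction. Leaving out 1 array gave 9 to 11 in WT, 7 to 10 in KO, 5 to 10 between the genotypes on the high cholesterol diet, 4 to 8 in the interaction and 0 on chow.

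Median scaling shifted the median of all genes by -0.12 on chow and -0.14 on the high cholesterol diet between the genotypes, and by -0.09 in WT and -0.11 in KO between the diets. Deviations of the 24 pairs of arrays with equal replicate numbers correlated across genes by -0.12 to 0.27, with a median of 0.01. The high cholesterol pairs of WT and KO had 0.22, 0.1, 0.26 and 0.27. Over both diets 11 of 16 arrays matched best with an array of their own number, more than unrelated numbers would be expected to give. A shared source of arrays with equal numbers therefore cannot be excluded, though no label gives one. The main p-values and the splits take no account of it. With the replicate number as a block the genes numbered 15 between the genotypes on the high cholesterol diet, 2355 between the diets in WT and 2608 in KO. A block on the slide was not run, because the files give no slide. Signal over background limits dim genes such as Met, detected on 7 of 16 arrays.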

Other observations

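None of the splits below was chosen only after the result was seen. Other splits of the 8 arrays of a comparison were counted, 35 in all with the real split. Between the diets chance can be excluded for the gene counts: 1 of 35 splits gave as many genes, the real one, with 2354 genes against at most 3 in WT and 2559 against at most 1 in KO. For the 10 lists in WT 1 of 35 splits gave as many, the real one, which is the smallest share that these splits allow. Other splits gave up to 8 lists, so the margin was small and chance is not clearly excluded there. For the 10 lists in KO chance cannot be excluded (7 of 35, up to 12).

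Between the genotypes on the high cholesterol diet chance cannot be excluded for the 15 genes by splits that ignore replicate numbers, since 2 of 35 gave as many, nor for the 6 lists, since 24 of 35 did, with up to 13. The split that set replicates 1 and 2 against 3 and 4 of both genotypes gave 161 genes, which points to a structure of the samples; with the replicate number as a block the count was 15. For the matrix list 1 of 35 splits gave a camera p as small as 1.79e-09, the real one, but the next smallest, 1.25e-08, was close. This list had the smallest camera p of all lists in the real split. The other splits were scored on it alone, which favours the real one. On chow the count of 0 leaves nothing to test, as all 35 of 35 splits reach it; the other splits gave at most 2 genes. In the fit on the chow arrays alone 1 of 35 gave 74, the real one, with at most 9 otherwise. This is the smallest share that the splits allow, and they ignore replicate numbers. Chance is therefore unlikely for that fit, but it was 1 of several alternatives and the main fit gave 0 genes. Of 100 splits for the interaction 13 gave at least 1 gene, with up to 567, and 53 gave at least 4 lists, with up to 11, so chance cannot be excluded for either. The split with 567 genes kept the real chow groups, and its cause was not tested.

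Several lists of lipid metabolism and oxidative stress did not pass camera between the diets in either genotype. With fry the list of antioxidant enzymes and metallothioneins passed in both (fry adjusted p = 0.032 in WT and 0.000218 in KO). The list of hepatocyte growth factor and MET signalling passed with fry in KO (fry adjusted p = 0.0211). In WT 1 of 14 fatty acid and triglyceride synthesis genes rose and 4 fell (camera adjusted p = 0.116), and 2 of 19 fatty acid oxidation genes rose and 3 fell (0.962). Of 11 lipid storage genes 2 rose and 1 fell (0.697), and of 14 lipoprotein genes 0 passed (0.724). Of 18 antioxidant enzyme and metallothionein genes 5 rose and 2 fell, or 6 and 2 adjusted over the list alone (0.664). Of 14 genes of hepatocyte growth factor and MET signalling 1 rose and 3 fell in WT (0.962), with a median of 0.12 but a mean of -0.04. Apart from the antioxidant list, these counts were equal when adjusted over the list alone.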
